A study of Homo sapiens with 12 samples.

How the data were processed

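Polyadenylated or rRNA-depleted RNA was sequenced from IGROV-1 and SK-OV-3 cells treated with DMSO or with EPZ-5676 at 10 µM for 48 h, 3 libraries per group and 12 in all. The sample protocols describe oligo-dT selection from total RNA and strand-marked libraries made with dUTP, whereas the series text names depletion of ribosomal RNA, so the selection step is uncertain. The deposited tables hold the raw count of reads per gene for each library, 1 table per line, with the same 26485 gene symbols in both. Per the submitters' processing notes, the tools were bcl2fastq 2.18.0.12, STAR 2.7.1a, HTSeq and DESeq2 1.28 with the genome build hg38, and the notes give no version for HTSeq. The gene annotation and the strand setting of the counting are not given in the sources used here. Reads of overlapping genes and of close copies, such as those of the AKR1C, CXCL and metallothionein genes, may therefore have been split, shared or lost. Per the labels' growth protocols IGROV-1 was grown in RPMI and SK-OV-3 in DMEM.

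Groups were taken from the sample titles and characteristics. Total counts ran from 20033197 to 31683936 per library. The floor of 3 counts, which covers counting error only, corresponds to 0.0947 to 0.15 CPM. No column of the tables was left out, and there were no summary lines to remove. Symbols were matched to RefSeq's GRCh38.p14 gene table, the assembly family of hg38, for coordinates. Of the 26485, 23758 matched by current symbol, 1562 by a single synonym and 1165 not at all, and 24593 had a transcript length in GENCODE release 29.

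Analyses used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with matplotlib 3.10.9. The deposited counts were tested per line with edgeR's robust quasi-likelihood test of EPZ-5676 against DMSO, with TMM scaling (factors from 0.9877 to 1.018), the filterByExpr filter (minimum count 10, minimum total 15), Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. The difference between the lines was tested in a fit of all 12 libraries as the change in SK-OV-3 minus that in IGROV-1. Calls shared by the lines were set against the overlap of independent lists and tested with Fisher's exact test. In total 49 gene lists with 1032 genes, 981 of them in the tables, were tested with camera at a preset inter-gene correlation of 0.01 and again with the estimated correlation, and with fry as a self-contained test. The genes that rose or fell in a line were tested as sets in the other line by the same test, adjusted over the 4 sets. Lists with at least 3 tested genes entered, 47 per line and 48 for the difference, and p-values were adjusted over them. With the estimated correlation 0 lists passed in either line and 1 passed in the difference. At the preset correlation camera also passed up to 6 lists per line when the libraries were regrouped across treatments. Lists that the report does not name did not pass with either correlation in a line or in the difference. Members of a list were counted over all genes tested and adjusted over the list alone, and some members that passed are not reported here by name. Log-CPM values used a prior count of 2, and levels are TMM-scaled CPM.

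The design, the lists, the alternatives and the rule for naming genes were chosen before the data were examined. The rule takes DOT1L always. Per line it takes the 8 largest rises and 8 largest falls among genes past 0.05 with a mean of at least 5 CPM and all treated libraries on the same side of all DMSO libraries. It takes up to 4 members with the smallest p of each list past 0.05 and up to 2 of other described lists, the 5 strongest shared genes per direction, and the 4 genes with the smallest p per direction of the difference. Genes with clone names are counted and not named. A few genes of the rule with the largest p-values were left out for length. Sex-linked transcripts were left out of every check of mixing.

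Alternatives were size factors by RLE, total counts alone, no filter on low counts, at least 1 CPM in 3 libraries, DESeq2, the replicate number as a block, each library left out in turn, a threshold of 0.01, all 12 libraries in a joint fit, scaling within each line, and for lists the estimated correlation. Chosen after seeing the data were the removal of each library's trend on transcript length (loess, span 0.5) and the omission of the 2 libraries with the steepest trend. Gene families with a shared symbol stem and at least 5 tested members were also tested after the data were seen.

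The code was tested on simulated data drawn from the libraries' own means and depths, with 100 genes changed at each of 2 folds. Of the genes changed 1.5-fold edgeR recovered 82% in IGROV-1 (14118 genes), 85% in SK-OV-3 (14659 genes) and 72% for the difference (13228 genes). Of those changed 2-fold it recovered 93%, 95% and 91%. False calls were 15 of 190, 12 of 192 and 9 of 172.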

Results

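RNA sequencing measured gene expression in IGROV-1 and SK-OV-3, a pair of established human ovarian carcinoma cell lines, after 48 h with the DOT1L inhibitor EPZ-5676 (pinometostat) at 10 µM or after the solvent DMSO, whose volume and time are not given in the sources used here and which was taken as the matched vehicle. DOT1L is a histone methyltransferase found on transcribed gene bodies, and the series asks what it does in the growth and progression of ovarian cancer. Each of the 4 groups held 3 libraries. The total counts in IGROV-1 were 20033197, 24402200 and 22850821 for DMSO replicates 1 to 3 and 31683936, 28380908 and 22096757 for EPZ-5676 replicates 1 to 3. In SK-OV-3 they were 27752948, 22585704 and 27414100 with DMSO and 27633654, 27371553 and 30023221 with EPZ-5676. Between 17150 and 17837 of the 26485 genes had at least 1 count in a library. ERBB2, the receptor gene amplified in SK-OV-3, stood at 3376 to 4021 CPM (counts scaled to library size) in the SK-OV-3 libraries and at 187.3 to 214.1 CPM in the IGROV-1 libraries, as the line names require.

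No pair of replicates agreed within sampling noise: the chi-square of their counts per degree of freedom ran from 1.44 to 20.3. The treated IGROV-1 replicate 3 stood apart, at 20.3 and 15.9 against the other treated libraries of its line, which differed by 3.49 from each other. In that library long transcripts were lower than in the mean of the DMSO libraries of its line (rank correlation with transcript length -0.463 across genes, which are not independent replicates), against 0.0797 and -0.0935 in the other treated libraries. In DMSO replicate 2 of SK-OV-3 long transcripts were lower than in the mean of the other DMSO libraries of its line (-0.42), from which it differed by 5.96 and 6.96, against 1.44 between them. The size of its trend was smaller, with medians of 0.0914 and -0.16 in the shortest and longest 10% of transcripts against 0.194 and -0.293 in the treated IGROV-1 replicate 3. The treated SK-OV-3 libraries differed by 5.00 to 12.4. Trends on the GC content of transcripts were as large in other libraries. Computed in the same way, the rank correlations with GC were 0.512 and -0.425 in IGROV-1 DMSO replicates 2 and 3 and 0.541 in SK-OV-3 EPZ-5676 replicate 2. No alternative removed a GC trend. The series text calls the replicates biological without saying whether they were separate cultures, so the p-values measure only the spread between these samples, which may be technical. Levels below are means ± SD in TMM-scaled CPM with n = 3 libraries per group, errors of log2 fold changes are standard errors, and adjusted p-values come from edgeR's quasi-likelihood test unless a list is named.

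The transcript of the drug's target, DOT1L (chromosome 19, 2163933 to 2232578), did not pass the test in either line. It stood at 101.7 ± 6.81 CPM with DMSO and 91.2 ± 8.13 CPM with EPZ-5676 in IGROV-1 (log2 fold change -0.16 ± 0.076, adjusted p = 0.308). In SK-OV-3 it stood at 63.52 ± 3.4 and 70.57 ± 7.18 CPM (0.15 ± 0.072, adjusted p = 0.552). The difference between the lines was 0.30 with an adjusted p of 0.215. The gene overlaps AP3D1 and PLEKHJ1 in the annotation. Histone methylation itself was not analysed here, so these transcript levels do not check that the enzyme was blocked.

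In IGROV-1, the comparison of EPZ-5676 with DMSO asked which genes depend on DOT1L activity in this line. The chemokine genes CXCL1 and CXCL3, whose products attract neutrophils, rose most among the genes above the level set for naming. CXCL1 (chromosome 4, 73869393 to 73871308) went from 2.406 ± 0.389 to 8.37 ± 1.11 CPM, a 3.43-fold rise (log2 1.78 ± 0.15, adjusted p = 1.28e-05). CXCL3 (chromosome 4, 74036589 to 74038689) went from 3.902 ± 0.444 to 12.93 ± 0.529 CPM, a 3.31-fold rise (log2 1.73 ± 0.11, adjusted p = 1.48e-06). These genes are close copies of each other, and reads shared between them could have been split or lost in counting. ANKRD1, a stretch-responsive gene, rose 2.61-fold from 23.01 ± 1.13 to 60.06 ± 0.703 CPM (adjusted p = 1.32e-07). Rises of 2.56-fold in SERPINB9, an inhibitor of granzyme B (adjusted p = 5.24e-05), of 2.39-fold in the sialyltransferase ST6GALNAC1 (1.6e-05), and of 2.32-fold in RASGRP1, an activator of RAS (3.93e-05), followed. SLC7A7, an amino acid transporter, rose by log2 1.12 to 29.67 ± 0.605 CPM (adjusted p = 5.41e-06) and FGFBP1, a carrier of fibroblast growth factors, 2.17-fold to 27.27 ± 2.34 CPM (6.81e-06).

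Among the largest falls in IGROV-1, the cell adhesion gene CEACAM1 (chromosome 19, 42507306 to 42528481) fell 3.73-fold, from 11.51 ± 0.451 to 3.078 ± 0.288 CPM (log2 -1.90 ± 0.12, adjusted p = 6.88e-07). The desmosomal cadherin gene DSC2 (chromosome 18, 31058840 to 31102421) fell 2.45-fold, from 87.32 ± 1.17 to 35.64 ± 2.47 CPM (log2 -1.29 ± 0.068, adjusted p = 1.51e-07). DLX6-AS1, a noncoding RNA that overlaps DLX6, fell 2.94-fold from 14.55 ± 1.02 to 4.896 ± 0.726 CPM (adjusted p = 5.17e-06). The lysophosphatidic acid receptor LPAR3 fell 2.16-fold (adjusted p = 2.56e-05), and FREM2, which encodes an extracellular matrix protein, 2.12-fold from 88.25 ± 4.1 to 41.52 ± 7.86 CPM (0.000202). SLC40A1, the iron exporter ferroportin, fell 2.08-fold from 46.25 ± 0.614 to 22.24 ± 1.2 CPM (adjusted p = 1.49e-06). Falls of 2.02-fold in the sodium-proton exchanger SLC9A2 (2.18e-05) and of 1.92-fold in the synaptic adhesion gene NLGN1 (0.000205) completed the set.

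Across IGROV-1, 656 of 14118 tested genes (4.65%) passed an adjusted p of 0.05, 424 higher and 232 lower with the drug. Of these, 94 changed by 2-fold or more, 82 up and 12 down, and the median absolute log2 fold change of the 656 was 0.465. DESeq2 called 653 genes, with another split of 352 higher and 301 lower. The count rested on single libraries: it was 333, 251 and 319 without DMSO replicates 1, 2 and 3, 404 without EPZ-5676 replicate 2, and 1521 without EPZ-5676 replicate 3. With each library's trend on transcript length removed it was 1248.

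Genes of inflammatory signalling rose together in IGROV-1. Of 19 tested cytokine genes and targets of the transcription factor NF-kB, 17 rose and 0 fell, both over all genes tested and adjusted over the list alone. The median log2 fold change was 0.825 and the mean 1.14 (limma's camera test, adjusted p = 1.46e-21, and adjusted p = 0.0628 with an estimated correlation). Beside CXCL1 and CXCL3 these included TNFAIP3, an inhibitor of NF-kB signalling, at 43.15 ± 0.889 and 76.43 ± 4.54 CPM (log2 0.83 ± 0.067, adjusted p = 8.05e-06). The cytokine IL32 rose from 26.67 to 45.93 CPM (0.78 ± 0.075, 3.21e-05). Chosen after their values were seen, CXCL8 rose from 1.089 to 4.529 CPM and CXCL2 from 1.532 to 6.232 CPM. The members that did not pass were TNFAIP2 at 0.04 and NFKB1 at 0.10. The 17 called members became 12 without DMSO replicate 1 or 2 and 18 without EPZ-5676 replicate 3, and DESeq2 called 15. Some of the 17 lay under 1 CPM with DMSO, among them CXCL5 (0.0915), CCL20 (0.18), IL1A (0.38), ICAM1 (0.538) and IL6 (0.718).

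Immediate early genes, the first to respond to growth factors and stress, rose as a list in IGROV-1. Of 17 tested, 6 rose and 0 fell (8 rose adjusted over the list alone), with a median of 0.231 (camera adjusted p = 5.2e-05, and adjusted p = 0.431 with an estimated correlation). The 6 rises became 3 without DMSO replicate 1 or 2 or EPZ-5676 replicate 2, and 2 without DMSO replicate 3. IER3 rose 1.72-fold from 28.61 to 49.33 CPM (adjusted p = 4.57e-05) and the transcription factor EGR1 rose from 38.5 to 50.94 CPM (0.40 ± 0.064, 0.002). ATF3 and JUN, which encode partners in the AP-1 complex, rose by log2 0.43 (adjusted p = 0.0133) and 0.32 (0.0334). Their calls ended without EPZ-5676 replicate 2 or DMSO replicate 3, that of ATF3 also without DMSO replicate 2 and that of JUN without DMSO replicate 1, at adjusted p-values between 0.0596 and 0.177.

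The integrated stress response and antioxidant genes moved the same way. Of 21 tested targets of ATF4, the transcription factor of amino acid shortage, 6 rose and 0 fell (13 and 1 adjusted over the list alone), with a median of 0.20 (camera adjusted p = 2.29e-05, and adjusted p = 0.207 with an estimated correlation). The 6 rises became 2 without DMSO replicate 2, 3 without DMSO replicate 3 and 4 without EPZ-5676 replicate 2, but 11, with 1 fall, without EPZ-5676 replicate 3 and 10, with 1 fall, with the transcript length trend removed. Asparagine synthetase, ASNS, rose from 89.38 to 118.9 CPM (0.41 ± 0.06, adjusted p = 0.00106), and VLDLR from 57.09 to 74.14 CPM (0.38 ± 0.068, 0.00475). CHAC1, which degrades glutathione, rose from 4.127 to 6.854 CPM (0.74 ± 0.14, 0.00583), a call that ended without DMSO replicate 2 (adjusted p = 0.0634, the highest of 14 alternatives whose lowest was 1.2e-05). Of 15 tested targets of NRF2, the oxidative stress factor, 4 rose and 0 fell (10 and 0 adjusted over the list alone), with a median of 0.22 (camera adjusted p = 0.000247, and adjusted p = 0.207 with an estimated correlation). They were the peroxiredoxin-reducing enzyme SRXN1 (167.7 to 209.8 CPM, adjusted p = 0.00383), the ferritin heavy chain FTH1 (1871 to 2360 CPM, 0.0125), thioredoxin reductase TXNRD1 (640.5 to 770.0 CPM, 0.0177) and heme oxygenase HMOX1 (0.32 ± 0.083, 0.0381). The calls of FTH1, TXNRD1 and HMOX1 ended without DMSO replicate 1, 2 or 3, and those of TXNRD1 and HMOX1 also without EPZ-5676 replicate 2 (adjusted p from 0.0713 to 0.202). The 4 called NRF2 targets became 1 without DMSO replicate 1, 2 or 3, and 9 without EPZ-5676 replicate 3.

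Of 15 tested genes of TGF-beta signalling in IGROV-1, 5 rose and 1 fell (7 and 2 adjusted over the list alone), with a median of 0.217 (camera adjusted p = 0.00784, and adjusted p = 0.431 with an estimated correlation). CYR61 and CTGF, which encode secreted matrix proteins, rose 1.4-fold from 187.1 to 261.7 CPM (adjusted p = 0.00019) and 2.41-fold from 1.393 to 3.415 CPM (0.00149). The ligand gene TGFB1 rose 2.38-fold from 1.738 to 4.203 CPM (0.000797). Chosen after their values were seen, ID2 rose by 0.38 (adjusted p = 0.00849), and the pathway inhibitor SMAD6 fell by 0.45 (0.00833). Both calls ended without DMSO replicate 2, at adjusted p-values of 0.0857 and 0.0934, the highest of their 14 alternatives, whose lowest were 0.000536 and 2.48e-05.

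All 14 tested genes of antigen presentation were higher in treated IGROV-1, and 3 passed (4 adjusted over the list alone). The median was 0.133 (camera adjusted p = 0.000644, and adjusted p = 0.207 with an estimated correlation). HLA-F, a nonclassical class I gene, rose from 3.233 to 5.429 CPM (adjusted p = 0.0112), the immunoproteasome subunit PSMB9 from 2.398 to 3.766 CPM (0.033) and the peptide transporter TAP1 from 29.64 to 35.83 CPM (0.0341). None of these calls held without DMSO replicate 2, and those of PSMB9 and TAP1 also ended without DMSO replicate 1 or 3 or EPZ-5676 replicate 2, and that of PSMB9 without EPZ-5676 replicate 1 (adjusted p from 0.0567 to 0.187). Among 26 tested interferon-stimulated genes, the guanylate-binding genes GBP2 (2.709 to 5.397 CPM, adjusted p = 0.000845) and GBP1 rose and the RNA sensor IFIT1 fell by 0.50 (21.67 to 15.39 CPM, 0.00224), and the list did not pass (median 0.0551, 3 up and 1 down adjusted over the list alone, camera adjusted p = 0.0744). GBP1, chosen after its values were seen, lay at 0.4872 and 1.153 CPM (adjusted p = 0.0378) and lost its call without any 1 of the DMSO libraries or EPZ-5676 replicate 2, at up to 0.195.

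Epithelial genes passed narrowly in IGROV-1: 4 of 23 rose and 0 fell (5 and 1 adjusted over the list alone), with a median of 0.0922 (camera adjusted p = 0.0495, and adjusted p = 0.572 with an estimated correlation). Keratin 18 (KRT18, which overlaps KRT8) rose from 528.5 ± 10.2 to 704.8 ± 61.7 CPM (adjusted p = 0.00245), and the tight junction gene CLDN1 from 585.1 ± 8.03 to 703.2 ± 32.4 CPM (0.0193). P-cadherin, CDH3, rose by 0.68 (0.0251) and the transcription factor OVOL2 by 0.74 (0.0409). The list's call ended without each of DMSO replicates 1 and 3 and EPZ-5676 replicates 1, 2 and 3 (adjusted p = 0.116, 0.131, 0.0744, 0.0571 and 0.122) and with the transcript length trend removed (0.173). Those of CLDN1, CDH3 and OVOL2 ended without DMSO replicate 2 or 3, those of CLDN1 and OVOL2 without DMSO replicate 1, that of CDH3 without EPZ-5676 replicate 1 and that of OVOL2 without EPZ-5676 replicate 2 (adjusted p from 0.0593 to 0.19). The 4 called members became 1 without DMSO replicate 2 or 3 and 9 without EPZ-5676 replicate 3.

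Another 3 lists were lower in treated IGROV-1. Of 34 histone methylating, demethylating, acetylating and deacetylating enzymes, 30 were lower, with a median of -0.118 (camera adjusted p = 0.000709, and adjusted p = 0.659 with an estimated correlation). No member passed by edgeR or DESeq2, over all genes tested or adjusted over the list alone, against 8 at an unadjusted p under 0.05. The closest were EZH2, the enzyme of Polycomb silencing, at -0.25 (adjusted p = 0.0713) and the deacetylase SIRT1 at -0.22 (0.0866). Without EPZ-5676 replicate 3, the library with the length trend, the median was -0.0419 and the call ended (adjusted p = 0.064), as it did with the trend removed (-0.0652, 0.232). Of 23 DNA repair genes, 19 were lower, with a median of -0.0935 (camera adjusted p = 0.0172, and adjusted p = 0.626 with an estimated correlation), and edgeR and DESeq2 called 0 of them against 2 at an unadjusted p under 0.05. XRCC3 lay at -0.23 (adjusted p = 0.11) and the checkpoint kinase CHEK1 at -0.21 (0.126). That call ended without EPZ-5676 replicate 3 (0.0777), without DMSO replicate 3 (0.13) and with the trend removed (0.213).

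Targets of the tumour suppressor p53 in IGROV-1 went down as a list, with 3 of 17 falling and 1 rising (6 and 1 adjusted over the list alone) and a median of -0.0873 (camera adjusted p = 0.00784, and adjusted p = 0.362 with an estimated correlation). FDXR, a mitochondrial reductase, fell by 0.30 (51.42 to 41.79 CPM, adjusted p = 0.0217), the repair gene DDB2 by 0.24 (0.0327) and TP53INP1 by 0.29 (0.037), whereas the growth arrest gene GADD45A rose by 0.33 (0.0206). The list's call ended without EPZ-5676 replicate 2 (adjusted p = 0.0571). The gene calls ended without DMSO replicate 1, 2 or 3, those of the falling genes also without EPZ-5676 replicate 2 and those of FDXR and DDB2 without EPZ-5676 replicate 1 (adjusted p from 0.0666 to 0.191).

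In SK-OV-3, the same question gave smaller changes. IGFBP5, a binding protein of insulin-like growth factors (chromosome 2, 216672105 to 216695549), rose 1.81-fold from 5.252 ± 0.321 to 9.512 ± 0.396 CPM (log2 0.85 ± 0.11, adjusted p = 8.08e-05). AKR1C2, an aldo-keto reductase of steroid metabolism (chromosome 10, 4987775 to 5018000), rose 1.57-fold from 18.57 ± 1 to 29.05 ± 0.995 CPM (0.65 ± 0.077, 3.6e-05). PTX3, a secreted pattern recognition protein, rose 1.51-fold (adjusted p = 0.0014) and IGFBP1 1.43-fold from 11.39 to 16.25 CPM (0.00316). S100P, a calcium-binding protein, and RASGEF1B rose 1.49-fold (0.00835) and 1.48-fold (0.00399), calls that ended without DMSO replicate 1 (adjusted p = 0.0725 and 0.0721, the highest of 14 alternatives each, whose lowest were 6.47e-05 and 8.23e-05). The collagenase gene MMP1 (chromosome 11, 102789919 to 102798160) fell 1.58-fold from 179.3 ± 4.18 to 113.5 ± 6.56 CPM (-0.66 ± 0.061, 8.53e-07). VAV3, a guanine nucleotide exchange factor, fell 1.68-fold from 18.24 ± 1.2 to 10.8 ± 0.885 CPM (4.68e-05), and PPP1R1B, a phosphatase inhibitor, 1.48-fold from 182.4 ± 8.78 to 122.8 ± 4.04 CPM (6.57e-06). A locus with a clone name, whose position was not matched here, had nearly the same levels as PPP1R1B, 177.7 and 121.7 CPM, and whether they share reads was not tested. The integrin gene ITGB6 fell 1.66-fold (0.00316) and lymphotoxin beta, LTB, 1.61-fold (0.00309). A pair of neighbours on chromosome 8, the noncoding LINC01111 (76406654 to 76524356) and the zinc finger gene ZFHX4 (76681247 to 76867281), fell 1.95-fold (0.0014) and 1.71-fold (0.00272).

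Over the whole of SK-OV-3, 123 of 14659 tested genes (0.839%) passed, 48 higher and 75 lower, and 1 changed by 2-fold or more. The median absolute log2 fold change of the 123 was 0.401, and the biological coefficient of variation was 0.0577 against 0.068 in IGROV-1. The count was 44, 78 and 64 without DMSO replicates 1, 2 and 3.

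Antioxidant and stress response genes rose as lists in SK-OV-3 too. Of 15 NRF2 targets, 1 rose (6 adjusted over the list alone), with a median of 0.13 (camera adjusted p = 5.6e-07, and adjusted p = 0.173 with an estimated correlation). It was the aldo-keto reductase AKR1C1, from 99.99 to 139 CPM (0.48 ± 0.059, adjusted p = 5.02e-05), a gene that lay at 0.02 in IGROV-1 (0.928) and shares long stretches of sequence with AKR1C2 and AKR1C3. Of 22 ATF4 targets, 3 rose and 0 fell (6 and 0 adjusted over the list alone), with a median of 0.0994 (camera adjusted p = 9.53e-07, and adjusted p = 0.562 with an estimated correlation). They were ATF3 (53.14 to 66.36 CPM, adjusted p = 0.00948), the secreted STC2 (56.01 to 68.83 CPM, 0.0172) and PPP1R15A, which ends the translational block (231.0 to 273.5 CPM, 0.0321). The gene calls ended without DMSO replicate 1 or 3, those of ATF3 and PPP1R15A also without EPZ-5676 replicate 1 and that of PPP1R15A without EPZ-5676 replicate 3 (adjusted p from 0.0656 to 0.274).

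Inflammatory genes in SK-OV-3 showed 3 rises and 1 fall among 23 (4 and 1 adjusted over the list alone), with a median of 0.0771 (camera adjusted p = 0.00408, and adjusted p = 0.562 with an estimated correlation). TNFAIP2 rose 1.33-fold from 87.12 to 116.3 CPM (adjusted p = 0.00121), the interleukin genes IL1A from 66.24 to 82.11 CPM (0.0193) and IL1B from 3.163 to 4.915 CPM (0.0382), and the chemokine CXCL5 fell from 324.6 to 270.5 CPM (0.0335). Leaving out DMSO replicate 3 or EPZ-5676 replicate 3 ended the list's call (adjusted p from 0.0525 to 0.129). The calls of IL1A, IL1B and CXCL5 ended without DMSO replicate 1 or 3, those of IL1A and IL1B without EPZ-5676 replicate 3, those of IL1A and CXCL5 without EPZ-5676 replicate 1 and that of CXCL5 without DMSO replicate 2 or EPZ-5676 replicate 2 (from 0.0581 to 0.243).

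Another 4 lists were slightly higher in treated SK-OV-3. Of 35 nuclear genes of the respiratory chain, 1 rose, the cytochrome c oxidase subunit COX7B (51.9 to 62.53 CPM, adjusted p = 0.0416, also 1 adjusted over the list alone), with a median of 0.0842 (camera adjusted p = 0.000407, and adjusted p = 0.74 with an estimated correlation). COX7B lost its call without DMSO replicate 1, 2 or 3 or EPZ-5676 replicate 1 or 3 (from 0.057 to 0.25), and the list with the transcript length trend removed (0.162). Of 22 genes of ribosome biogenesis, 21 were higher, with a median of 0.0519 (camera adjusted p = 0.0121, and adjusted p = 0.562 with an estimated correlation), RRP9 at 0.15 and DKC1 at 0.10 among them. Of 13 amino acid transporters the median was 0.0681 (camera adjusted p = 0.0261, and adjusted p = 0.64 with an estimated correlation), with 2 rises adjusted over the list alone and SLC7A5, the large neutral amino acid transporter, at 2243 and 2548 CPM (adjusted p = 0.213). Of 17 genes of antigen presentation the median was 0.0914 (camera adjusted p = 0.0313, and adjusted p = 0.74 with an estimated correlation), with PSMB10 at 0.23 and TAP2 at 0.16. In these last 3 lists edgeR and DESeq2 called 0 genes over all genes tested, against 1, 3 and 2 at an unadjusted p under 0.05. Leaving out DMSO replicate 3 or EPZ-5676 replicate 3 ended the call of ribosome biogenesis (0.0606 to 0.129), DMSO replicate 2 or EPZ-5676 replicate 1 that of the transporters (0.0782 to 0.177), and DMSO replicate 1 or 3 or EPZ-5676 replicate 2 that of antigen presentation (0.0992 to 0.158).

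**Figure D1:**
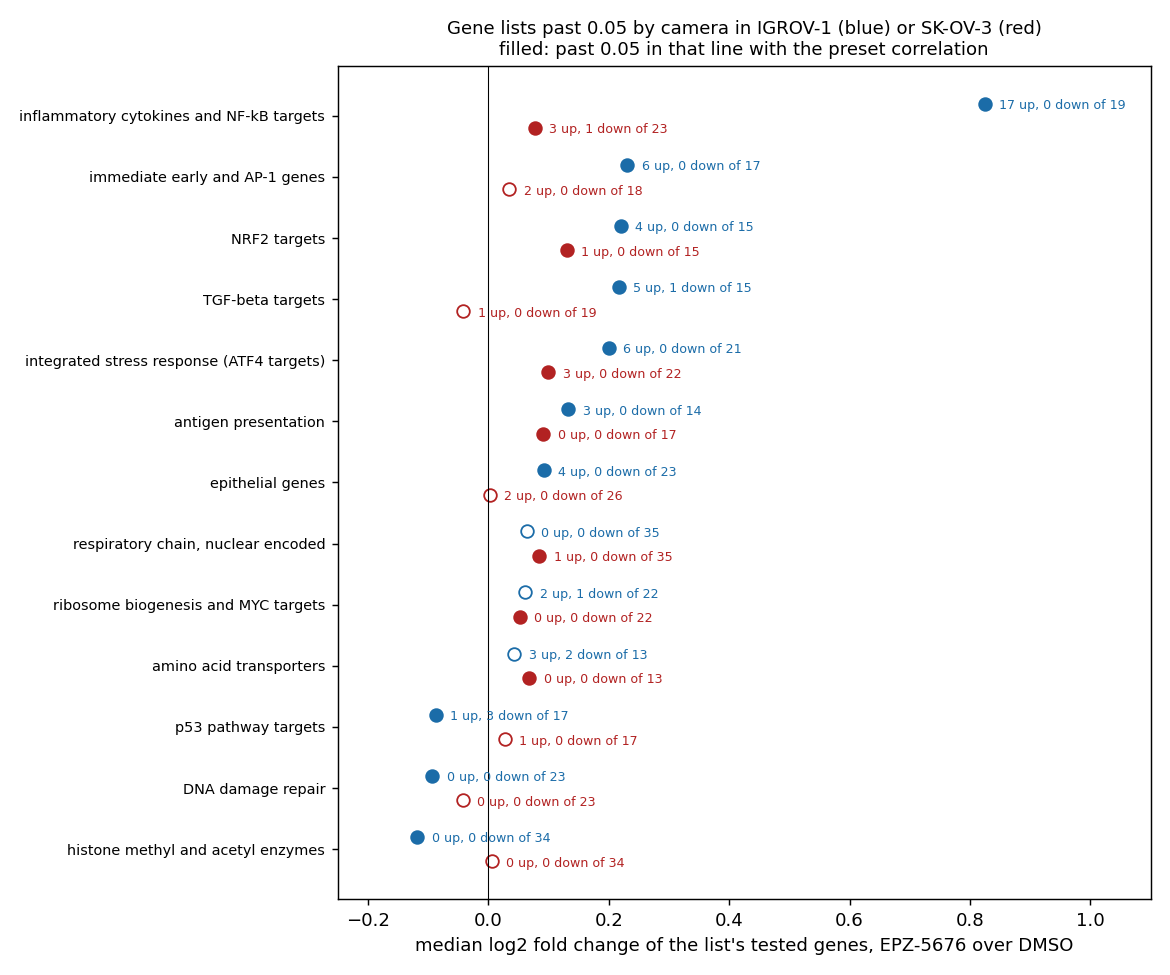
Median log2 fold change (EPZ-5676 over DMSO, horizontal axis) of the tested genes of each of the 13 lists past 0.05 by camera in IGROV-1 (blue) or SK-OV-3 (red). Filled circles passed in that line with the preset correlation, open circles did not, and the text beside each circle counts members past an adjusted p of 0.05. The inflammatory list stands at 0.825 in IGROV-1 and 0.0771 in SK-OV-3.

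Lists tied to DOT1L itself or to the tissue of origin did not pass in either line. DOT1L and its partners in transcription elongation had a median of -0.0952 over 16 genes in IGROV-1 (camera adjusted p = 0.091) and 0.0118 over 17 genes in SK-OV-3 (0.684). In both lines edgeR called 0 of them, with 1 and 4 at an unadjusted p under 0.05, and DESeq2 called 0 in IGROV-1 and 1 lower in SK-OV-3. The nearest were the cyclin CCNT2 at -0.21 in IGROV-1 (adjusted p = 0.151) and the elongation factor ELL2 at -0.25 in SK-OV-3 (0.0546). Among the HOX genes and other targets of MLL fusions, which need DOT1L in leukaemia, 2 of 13 fell and 1 rose in IGROV-1 (3 and 1 adjusted over the list alone, median -0.0341, camera adjusted p = 0.261). The HOX cofactor genes MEIS2 and PBX3 fell 1.5-fold from 68.88 to 45.81 CPM (adjusted p = 6.44e-05) and 1.73-fold from 18.3 to 10.55 CPM (0.000256). RUNX2, chosen after its values were seen, rose by 0.57 (0.0412), a call lost without any 1 library other than EPZ-5676 replicate 3 (0.0665 to 0.19). In SK-OV-3 edgeR and DESeq2 called 0 of 21, against 4 at an unadjusted p under 0.05 (median -0.0882, camera adjusted p = 0.172), with MEIS1 at -0.28.

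Of the ovarian carcinoma lineage genes, 1 of 12 fell in each line (3 and 1 adjusted over the list alone). LHX1 fell 1.44-fold in IGROV-1 from 100.2 to 69.54 CPM (adjusted p = 0.000327), and MECOM 1.3-fold in SK-OV-3 from 438.4 to 337.2 CPM (0.00121), with MECOM at -0.22 in IGROV-1 (0.0671). PAX8, the Müllerian lineage factor, stood at 798.2 and 681.8 CPM in IGROV-1 (0.0609). The lists did not pass (camera adjusted p = 0.56 and 0.151), with a median of -0.073 in SK-OV-3 and in IGROV-1 a median of 0.00553, a mean of -0.00657 and a test direction downward. Among integrins and laminins, 2 of 20 rose in IGROV-1 (5 up and 3 down adjusted over the list alone), among them the laminin chain LAMB3 (49.66 to 69.53 CPM, 0.000437). There the list's median was -0.0147, its mean 0.0784 and its test direction upward (camera adjusted p = 0.697). In SK-OV-3, ITGB6 alone of 21 fell (2 adjusted over the list alone, median -0.0242, camera adjusted p = 0.433).

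Among 28 genes of G2/M and mitosis edgeR and DESeq2 called 0 in either line, with 2 in IGROV-1 and 0 in SK-OV-3 at an unadjusted p under 0.05. Their median was 0.0109 with a mean of -0.000355 in IGROV-1 (test direction downward, camera adjusted p = 0.937) and -0.0456 in SK-OV-3 (0.35). Among 28 genes of G1/S and DNA replication, the cyclin CCND2 rose 1.71-fold in IGROV-1 from 25.98 ± 1.45 to 44.39 ± 0.695 CPM (adjusted p = 2e-05), and E2F2 lay at -0.29 (0.0625) and was the 1 member lower adjusted over the list alone, beside CCND2 as the 1 higher. At an unadjusted p under 0.05 there were 8 members in IGROV-1. The list did not pass in IGROV-1 (median -0.0611, camera adjusted p = 0.211) or in SK-OV-3 (0.013, 0.304), where edgeR and DESeq2 called 0 members, against 2 at an unadjusted p under 0.05. Of 10 cyclin-dependent kinase inhibitors and pocket protein genes, 1 rose and 1 fell in IGROV-1 (1 and 2 adjusted over the list alone): CDKN2B went from 2.933 to 4.756 CPM (adjusted p = 0.0116) and CDKN1B from 119.8 to 99.83 CPM (0.0236), both chosen after their values were seen. CDKN2B lost its call without DMSO replicate 2 (0.0964), and CDKN1B its call without any 1 library but EPZ-5676 replicate 3 (0.0652 to 0.158). Their list had a median of -0.0614, a mean of 0.0572 and a test direction downward in IGROV-1 (camera adjusted p = 0.842). In SK-OV-3 edgeR and DESeq2 called 0 of 9, against 2 at an unadjusted p under 0.05 (median -0.103, camera adjusted p = 0.304).

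Markers of other cell types were tested as lists for foreign RNA. The summed leukocyte markers stood at 62.42 ± 5.59 and 54.12 ± 4.05 CPM in IGROV-1, nearly all of it CD68 (59.4 and 50.1 CPM), which carcinoma lines also express, and at 25.45 and 22.83 CPM in SK-OV-3. The summed endothelial markers were 39.23 and 42.02 CPM in IGROV-1 and 8.803 and 7.837 CPM in SK-OV-3, the stromal markers 39.39 and 43.04 CPM and 42.34 and 39.95 CPM, and the mesothelial markers 40.71 and 38.04 CPM and 23.37 and 20.56 CPM. Erythroid and liver transcripts summed to 1.115 and 1.924 CPM in IGROV-1 and 9.269 and 10.7 CPM in SK-OV-3. No marker list passed by camera (adjusted p from 0.227 to 0.866 in IGROV-1 and from 0.496 to 0.749 in SK-OV-3), the erythroid and liver list having too few tested genes. Single markers did change in IGROV-1, in both directions: the leukocyte marker CD8A rose from 0.3113 to 0.8469 CPM (adjusted p = 0.0243), and of the stromal markers COL1A1 rose from 21.2 to 26.55 CPM (0.0334) and POSTN fell from 2.099 to 0.5227 CPM (0.00188). The calls of CD8A and COL1A1 ended without any 1 library other than EPZ-5676 replicate 3 (adjusted p from 0.0661 to 0.192).

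The difference between the lines was tested in a fit of all 12 libraries, as the change in SK-OV-3 minus that in IGROV-1. The inflammatory genes separated the lines most clearly. CXCL3 had a difference of -1.90 ± 0.12 (adjusted p = 6.89e-09) and stood at 40.25 and 35.72 CPM in SK-OV-3, above its level in either IGROV-1 group. CXCL1 had a difference of -1.82 (4.9e-07), with 127.2 and 124.5 CPM in SK-OV-3, and SERPINB9 one of -1.54 ± 0.14 (5.36e-07), with 77.36 and 68.65 CPM. SERPINE2, a protease inhibitor, rose 3.21-fold in IGROV-1 from 1.575 to 5.054 CPM (adjusted p = 5.74e-05) and lay at 315.4 and 300.9 CPM in SK-OV-3, a difference of -1.76 (5.36e-07). In the other direction, DSC2 had a difference of 1.27 ± 0.11 (3.57e-07), with 32.95 and 32.79 CPM in SK-OV-3, and SLC9A2 one of 1.12 ± 0.12 (6.69e-06). DCLK1, a microtubule-linked kinase, fell 1.75-fold in IGROV-1 from 265.1 ± 6.82 to 151.5 ± 13.1 CPM and stood at 38.99 and 40.83 CPM in SK-OV-3 (difference 0.86 ± 0.094, 1.01e-05). Ornithine decarboxylase, ODC1, fell 1.45-fold in IGROV-1 from 280.8 to 193.3 CPM and stood at 281.3 and 304.2 CPM in SK-OV-3 (0.64 ± 0.075, 2.44e-05).

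In all, 331 of 15662 genes (2.11%) differed in response, 64 with a higher and 267 with a lower change in SK-OV-3, and 79 of them by 2-fold or more (6 and 73). The count was 203, 219 and 220 without IGROV-1 DMSO replicates 1, 2 and 3, 199 without SK-OV-3 DMSO replicate 1 and 204 without SK-OV-3 EPZ-5676 replicate 1, and 555 with the transcript length trend removed. The lines grew in different media, RPMI for IGROV-1 and DMEM for SK-OV-3, so a difference of line and of medium cannot be separated here.

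Of the lists, the inflammatory genes responded less in SK-OV-3: 13 of 23 had a lower and 1 a higher change (15 and 1 adjusted over the list alone), with a median difference of -0.637 (camera adjusted p = 1.08e-14, and adjusted p = 0.000916 with an estimated correlation). The median was -0.318 for 19 TGF-beta genes (4 lower, or 9 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.002, and adjusted p = 0.278 with an estimated correlation). For 18 immediate early genes it was -0.152 (4 lower, also adjusted over the list alone, 0.0056, and adjusted p = 0.532 with an estimated correlation), a call that ended without IGROV-1 DMSO replicate 3 (0.0604) and without both libraries of steepest length trend, IGROV-1 EPZ-5676 replicate 3 and SK-OV-3 DMSO replicate 2 (0.0595). The histone enzymes had a median of 0.126 (0.00361, and adjusted p = 0.602 with an estimated correlation), and without those same libraries one of -0.0156 (0.57). Their call also ended without IGROV-1 EPZ-5676 replicate 3 alone (0.0882) and with the length trend removed (0.0554). The p53 targets had a median of 0.128 (0.037, and adjusted p = 0.278 with an estimated correlation), a call that ended without DMSO replicate 3 of either line, IGROV-1 EPZ-5676 replicate 2 or SK-OV-3 DMSO replicate 1 (0.0755 to 0.165). In the histone and p53 lists edgeR called 0 genes, against 4 and 2 at an unadjusted p under 0.05, and DESeq2 called 1 higher and 0.

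**Figure D2:**
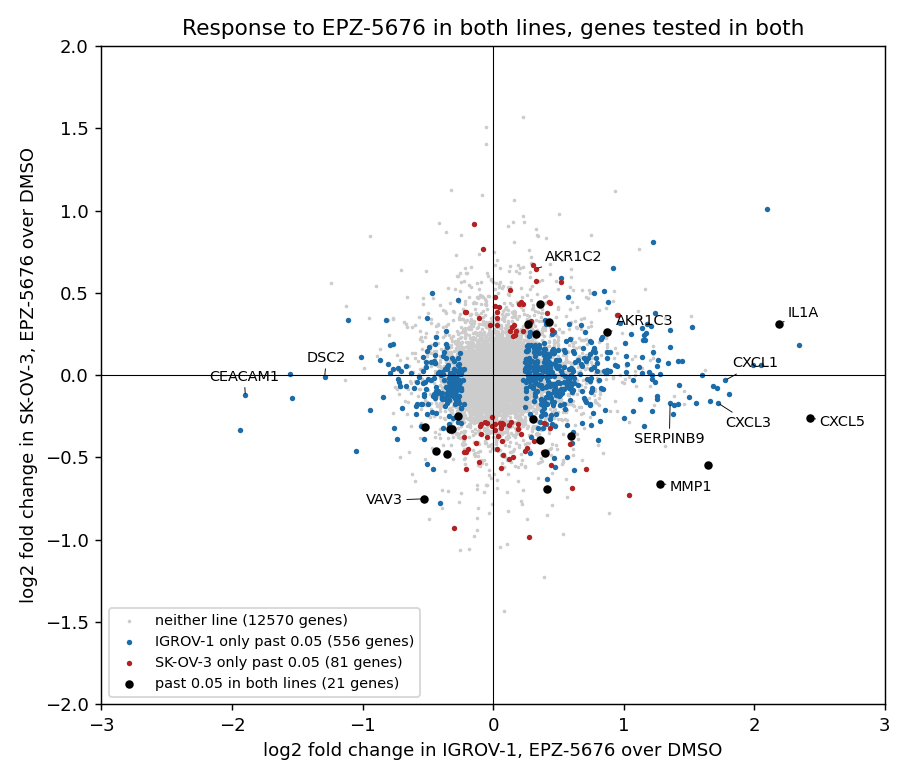
Log2 fold change of EPZ-5676 over DMSO in IGROV-1 (horizontal axis) and SK-OV-3 (vertical axis) for the 13228 genes tested in both lines, 1 point per gene, coloured by the line or lines in which the gene passed an adjusted p of 0.05. CXCL1, CXCL3, SERPINB9, DSC2 and CEACAM1 lie near 0 on the SK-OV-3 axis, and VAV3 is low on both axes.

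The calls of the lines, which share no control libraries, overlapped more than independent lists would. That expectation takes genes as independent and equally easy to call, and the overlap in opposite directions was in excess too (8 genes against 1.74 expected). The overlap alone therefore does not show a shared response. Among 13228 genes tested in both lines, 6 rose in both against 1.12 expected (Fisher's exact test, one-sided, p = 0.000801) and 7 fell in both against 0.966 (Fisher's exact test, one-sided, p = 4.78e-05). The genes that rose included AKR1C3, a prostaglandin and androgen reductase, at 11.4 and 20.83 CPM in IGROV-1 (log2 0.87 ± 0.097, adjusted p = 9.53e-05) and 211.1 and 252.5 CPM in SK-OV-3 (0.26 ± 0.058, 0.0269). ATF3 rose by 0.43 and 0.32, the metallothionein MT2A by 0.36 (0.0491) and 0.43 (0.00217), CLDN1 by 0.27 (0.0193) and 0.31 (0.00538), and GADD45A by 0.33 (0.0206) and 0.25 (0.0493). The sixth, chosen after its values were seen, was IL1A, at 0.3797 and 1.798 CPM in IGROV-1. VAV3 fell in both, in IGROV-1 from 206.3 ± 8.92 to 142.9 ± 3.03 CPM (-0.53 ± 0.059, 0.000102). The cell junction gene CGNL1 had changes of -0.44 (0.0112) and -0.46 (0.00733) in IGROV-1 and SK-OV-3, NLGN4X of -0.35 (0.0253) and -0.48 (0.00238), the pyrimidine-degrading enzyme DPYD of -0.33 (0.00962) and -0.33 (0.00538), and the transcription factor TFAP2A of -0.32 (0.0056) and -0.33 (0.0146). ARID5B and HOXB3, chosen after their values were seen, fell as well.

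VAV3 kept its call in both lines whichever library was left out, and the other genes named here did not. In IGROV-1, leaving out DMSO replicate 2 ended the calls of CGNL1, TFAP2A, ATF3, CLDN1, DPYD, GADD45A, MT2A and NLGN4X. DMSO replicate 3 ended those of the last 6 of these, DMSO replicate 1 those of the last 5, and EPZ-5676 replicate 2 those of ATF3, MT2A and NLGN4X (adjusted p from 0.0503 to 0.202). In SK-OV-3, DMSO replicate 1 ended the calls of ATF3, CLDN1, AKR1C3, GADD45A, CGNL1 and DPYD, and DMSO replicate 3 those of ATF3, AKR1C3, GADD45A and TFAP2A. EPZ-5676 replicate 1 ended those of ATF3, AKR1C3 and TFAP2A, DMSO replicate 2 that of TFAP2A, and EPZ-5676 replicates 2 and 3 that of GADD45A (from 0.0525 to 0.431). IL1A, ARID5B and HOXB3 lost their SK-OV-3 calls without DMSO replicate 1 or 3. The 13 shared genes became 7, 4 and 6 without IGROV-1 DMSO replicates 1, 2 and 3, 21 without IGROV-1 EPZ-5676 replicate 3, 4, 6 and 8 without SK-OV-3 DMSO replicates 1 and 3 and EPZ-5676 replicate 1, and 23 with the length trend removed. AKR1C3 rose less in SK-OV-3 than in IGROV-1 (difference -0.62, adjusted p = 0.00162).

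Some genes moved in opposite directions. A further 8 rose in IGROV-1 and fell in SK-OV-3, against 1.74 expected (Fisher's exact test, one-sided, p = 0.00032), and 0 did the reverse, against 0.623 expected. Other settings changed the count of 8, to 4 by DESeq2, 5 with at least 1 CPM in 3 libraries, 10 with total count only or without the low-count filter, and 11 with the transcript length trend removed, where 2 did the reverse. With the replicate number as a block the count was 2, although these numbers did not pair the libraries. MMP1 rose in IGROV-1 from 0.859 to 2.089 CPM (2.43-fold, adjusted p = 0.00252) and fell in SK-OV-3 from the far higher level given above, a difference of -1.95. The others, chosen after their values were seen, were the chemokines CXCL5 and CX3CL1, the calcium-binding CALB1, CCBE1, the asparaginase ASRGL1, the heat shock gene HSPA2 and the clone-named locus with the levels of PPP1R1B. CXCL5 stood at only 0.0915 and 0.505 CPM in IGROV-1. By a test chosen after the results were seen, SK-OV-3 RNA carried into the treated IGROV-1 libraries would give 65.7% of that rise, 21.5% of the rise of the clone-named locus, 20.4% for CALB1, 12.7% for MMP1 and at most 0.391% for the other 4. The share carried over was judged from 20 genes that include CXCL5 and the locus, each left out of its own estimate. The rises of these 20 ran from -0.0227% to 0.36% of their SK-OV-3 levels, whereas carried RNA would give a common share. The percentages above are therefore uncertain. CX3CL1 changed by 0.41 and -0.70, CALB1 by 0.60 and -0.37 and HSPA2 by 0.40 and -0.47 in IGROV-1 and SK-OV-3. CX3CL1 lost its SK-OV-3 call without any 1 of the 6 libraries, CXCL5 and HSPA2 theirs without any 1 library but EPZ-5676 replicate 3, ASRGL1 without any 1 but EPZ-5676 replicate 2, and CCBE1 without replicate 1 of either group (adjusted p from 0.0553 to 0.296). In IGROV-1 the calls of CCBE1 and CX3CL1 ended without any 1 library but EPZ-5676 replicate 3, those of CALB1 and CXCL5 without any 1 DMSO library, that of CALB1 also without EPZ-5676 replicate 1 and that of CXCL5 without EPZ-5676 replicate 2. That of ASRGL1 ended without DMSO replicate 2 or 3 and that of the clone-named locus without DMSO replicate 2 (adjusted p over these from 0.0547 to 0.171).

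As whole sets, the 371 genes that rose in IGROV-1 were not shifted in SK-OV-3, with 190 higher there and a median of 0.00637 (camera adjusted p = 0.635). Of the 206 that fell in IGROV-1, 136 (66%) were lower in SK-OV-3, with a median of -0.0561 (camera adjusted p = 0.00012, and adjusted p = 0.108 with an estimated correlation). Of the 40 genes that rose in SK-OV-3, 34 (85%) were higher in IGROV-1, with a median of 0.204 (camera adjusted p = 5.44e-06, and adjusted p = 0.0207 with an estimated correlation). Genes that rose in SK-OV-3 had short transcripts, with a median length of 2124 against 3585 over the tested genes. Short transcripts were also higher in treated IGROV-1 (rank correlation with length -0.252). These set tests were not repeated with the length trend removed or with libraries left out. The set of 62 genes that fell in SK-OV-3 did not pass in IGROV-1, where 39 (62.9%) were higher, with a median of 0.0654 (camera adjusted p = 0.107). Across the 13228 genes, which are not independent replicates, the fold changes of the lines had a Pearson correlation of 0.0573 and a Spearman correlation of 0.0876.

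**Figure D3:**
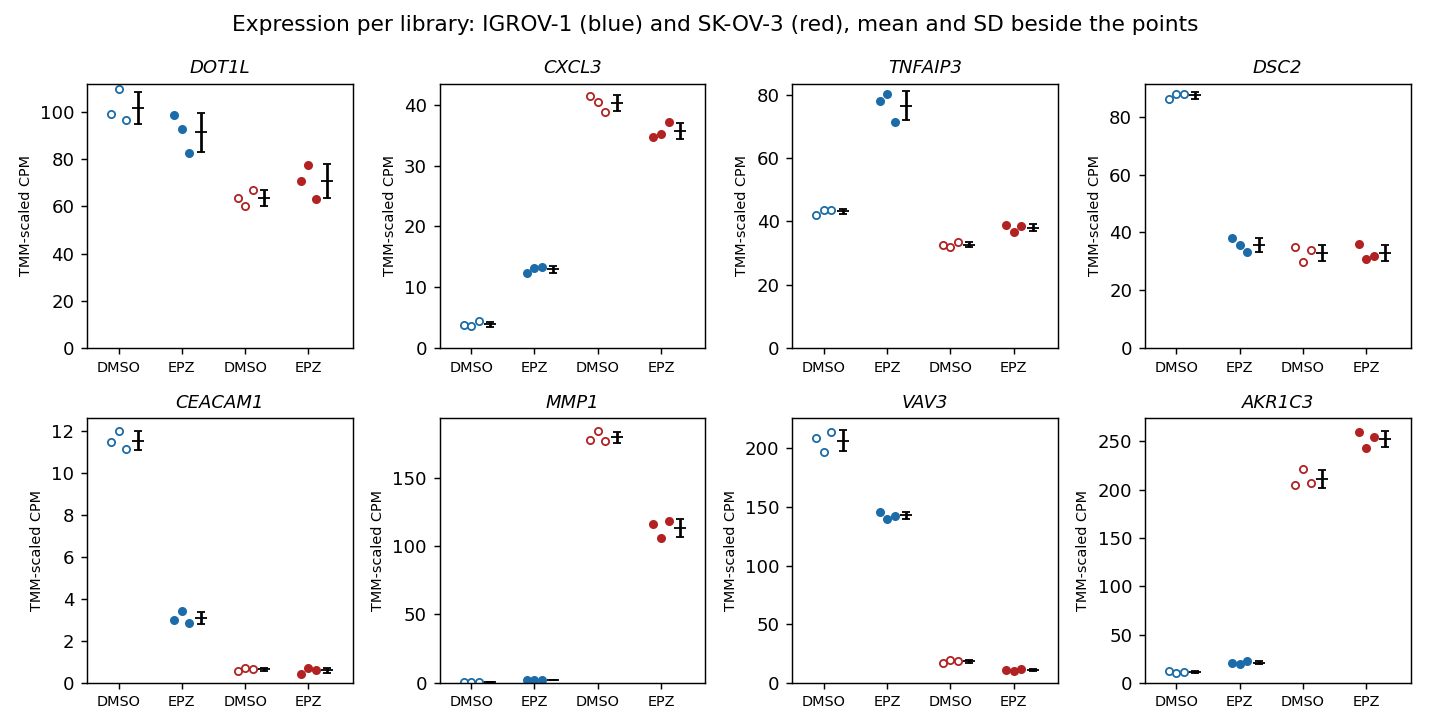
Expression per library in TMM-scaled CPM of DOT1L, CXCL3, TNFAIP3, DSC2, CEACAM1, MMP1, VAV3 and AKR1C3, in IGROV-1 (blue) and SK-OV-3 (red), with DMSO as open and EPZ-5676 as filled circles and the mean and SD of each group of 3 beside the points. DSC2 falls from a mean of 87.32 to 35.64 CPM in IGROV-1 and stands at 32.95 and 32.79 CPM in SK-OV-3, whereas VAV3 falls in both lines.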

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

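The tests of the length trend in IGROV-1 without EPZ-5676 replicate 3 and among its treated libraries, the removal of that trend, the test of power in SK-OV-3 and the tests of carried-over RNA for single genes were chosen only after the results were seen, and the other tests in this part were chosen before. The results in this part stood out because the response to EPZ-5676 differed between the lines by the test of the difference itself, except the trend with transcript length, which was noticed within IGROV-1.

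The inflammatory list rose in IGROV-1 and less in SK-OV-3, with a median difference of -0.637 (camera adjusted p = 1.08e-14, and adjusted p = 0.000916 with an estimated correlation). With DMSO some members already stood far higher in SK-OV-3 than in IGROV-1, such as CXCL8 (136.7 against 1.09 CPM) and ICAM1 (144.8 against 0.538 CPM). Others stood lower there, such as BIRC3 (55.26 against 278 CPM) and TNF (2.349 against 18.8 CPM). Whether the smaller change in SK-OV-3 depends on these starting levels was not tested. A deviant library could have made the rise, but without EPZ-5676 replicate 3 the median in IGROV-1 was 0.872 against 0.825 with it (camera adjusted p = 1.57e-18, range over 9 alternatives 1.55e-21 to 3.08e-17). The transcript length trend did not account for the rise, since with the trend removed the median was 0.851 (camera adjusted p = 1.59e-19). SK-OV-3 RNA carried into the treated IGROV-1 libraries, judged from 20 genes high in SK-OV-3 and nearly absent in IGROV-1, would give 0.425% of the list's summed rise of 337 CPM and under 25% of the rise of 16 of its 17 called members (median 0.487%, ICAM1 17%). For CXCL5 it would give 65.7% of the rise and stays open, but the share behind that value is not firm. Carried RNA would raise all 20 genes by a common share. Their rises ran from -0.0227% (IFI16) to 0.36% (ZDHHC2) of their SK-OV-3 levels, with 0.00884% for CYP1B1, the highest of them in SK-OV-3. These genes lie near the floor in IGROV-1, so the share cannot decide the case of CXCL5. The same holds for ICAM1, whose whole rise was 0.513% of its SK-OV-3 level. For the list without CXCL5 and ICAM1 a response of IGROV-1 to the drug, the biological explanation in the design, stays open as a hypothesis, and its cause was not tested.

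Long transcripts were lower in treated IGROV-1 (rank correlation of log2 fold change with transcript length -0.252 across genes, which are not independent replicates). EPZ-5676 replicate 3 alone is a candidate explanation, since without it the correlation was -0.00555. That value largely follows from the trends already seen in the single libraries, -0.463 in replicate 3 against 0.0797 and -0.0935, and is not a separate test. The GC content of the transcripts did not account for the trend of that library, whose partial correlation given GC was -0.449. An effect of the drug in all treated IGROV-1 libraries was argued against by the highest of their own correlations, 0.0797. In SK-OV-3 the correlation was -0.0732 with all libraries and -0.242 without DMSO replicate 2, and the treated libraries had 0.142, -0.165 and -0.0768 against a DMSO mean that holds replicate 2, so no cause was weighed there.

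IGROV-1 had 656 changed genes and SK-OV-3 had 123, and 331 genes differed in response. Lower power in SK-OV-3 might have hidden like changes, but the 371 genes that rose in IGROV-1 by a median of 0.485 had a median of 0.00637 in SK-OV-3, with quartiles of -0.103 and 0.105. The 0.485 may be too high, as these genes were chosen by the same data. Of the 206 that fell in IGROV-1, 136 were lower in SK-OV-3 (median -0.0561, camera adjusted p = 0.00012, and adjusted p = 0.108 with an estimated correlation), so weaker like falls may lie below the threshold. Standard errors in SK-OV-3 were 0.942 times those in IGROV-1 at the median over all genes tested in both lines, and 0.983 times over those called in IGROV-1. EPZ-5676 replicate 3 alone was not the source of the larger count either, since without it IGROV-1 had 1521 changed genes. The lines and their media stay open as explanations and could not be separated.

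With 3 libraries per group there are 10 splits per line, too few for a share under 0.05. The real split gave 656 genes in IGROV-1 and 123 in SK-OV-3, and the highest other split gave 0 in each line, so 1 of 10 splits was as large. For the lists the real split gave 10 and 7 past the threshold and the highest other 6 and 6, again 1 of 10 splits. The other splits, none of which called a gene, passed 1 to 6 lists in IGROV-1 and 0 to 6 in SK-OV-3. A list past the threshold at the preset correlation is therefore no sign of a treatment effect by itself. Over both lines 100 of 200 splits were drawn. For the difference 2 of 100 gave as many genes, the other being the split that keeps both real groupings and mirrors SK-OV-3, with 504 genes, which rests on the same grouping of the samples as the real split. For the shared genes 1 of 100 gave as many as 13, the highest other being 8. Both shares are under 0.05, which speaks only against the case that the groups differed in neither line and the libraries were exchangeable. If the libraries of a group shared a culture, a difference between cultures would give the same shares without a response to the drug. The splits cannot tell these cases apart. Since no other split of a line called a gene, the splits that regrouped either line had to give 0 shared genes, and the overlap itself is not tested by them. For the difference, the splits that kept the grouping of IGROV-1 and regrouped SK-OV-3 gave 173, 219 and 222 genes.

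Among lists, the median difference, SK-OV-3 minus IGROV-1, was 0.126 for histone enzymes, 0.128 for p53 targets, -0.152 for immediate early genes and -0.318 for TGF-beta genes. Among the 73 genes with a lower change in SK-OV-3 by at least 1 log2 unit, as SK-OV-3 minus IGROV-1, those named here were CXCL1 at -1.82, CXCL2 at -1.93, CXCL3 at -1.90, CXCL5 at -2.70, CXCL8 at -1.99, IL1A at -1.88, CX3CL1 at -1.12, ANKRD1 at -1.57, SERPINB9 at -1.54, SERPINE2 at -1.76, SLC7A7 at -1.28, FGFBP1 at -1.08, ITGB6 at -1.78, MMP1 at -1.95, MMP7 at -1.21, PPP1R1B at -1.29, TGFB1 at -1.38, CTGF at -1.18, GBP2 at -1.27, ABCG2 at -1.93, KIT at -1.03 and CD8A at -1.50. PPP1R1B stood at only 0.365 and 0.614 CPM in IGROV-1 and is among the 20 genes from which carried-over RNA was judged. Among genes with a smaller negative difference, those named here were RASGRP1 at -0.92, AKR1C3 at -0.62, ASNS at -0.33, VLDLR at -0.34, CHAC1 at -0.55, HLA-F at -0.62, TNFAIP3 at -0.61, IL32 at -0.65, IER3 at -0.69, EGR1 at -0.54, CYR61 at -0.44, ID2 at -0.58, KRT18 at -0.36, CDH3 at -0.63, OVOL2 at -0.78, SLC1A4 at -0.40, ASRGL1 at -0.58, CALB1 at -0.97, CCBE1 at -0.76, CDKN2B at -0.86, HSPA2 at -0.88, ELL2 at -0.58, RUNX2 at -0.61, LAMB3 at -0.40, ITGB8 at -0.58 and ALDH1A3 at -0.56. Among the 64 genes with a positive difference, those named here were CEACAM1 at 1.77, DSC2 at 1.27, LPAR3 at 1.44, POSTN at 1.60, SLC9A2 at 1.12, DCLK1 at 0.86, ODC1 at 0.64, PBX3 at 0.79, SLC38A1 at 0.46, AKR1C1 at 0.45, LHX1 at 0.40, TNFAIP2 at 0.36 and HOXB9 at 0.33.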

How the results depend on the processing

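The removal of the transcript length trend and the omission of the 2 libraries with the steepest trend were chosen after seeing the data. In 61 of 93 alternatives the counts of genes and lists stayed within 1.5 times the reported ones, and in 32 they did not. Leaving out 1 library gave 251 to 1521 genes in IGROV-1 (656 reported), 44 to 123 in SK-OV-3 (123), 199 to 429 for the difference (331) and 4 to 21 shared genes (13). Fewer samples give a test less power, whereas the rise to 1521 came without IGROV-1 EPZ-5676 replicate 3, the library with the length trend. An adjusted p under 0.01 left 292, 52, 147 and 2. Removing the length trend gave 1248 genes in IGROV-1, 555 for the difference and 23 shared genes, and without the low-count filter 21 genes were shared. With the estimated correlation 0 lists passed in IGROV-1 and 0 in SK-OV-3, whose camera tests with the preset correlation gave 10 and 7. Replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated by -0.0157, -0.000433 and -0.0486 in IGROV-1 and 0.0432, 0.041 and -0.00914 in SK-OV-3, and not every library correlated best with its own number. With the replicate number as a block 489 genes passed in IGROV-1, 72 in SK-OV-3, 345 for the difference, 8 in both lines and 2 in opposite directions (8 reported), and 9 and 7 lists, the epithelial genes in IGROV-1 being lost (adjusted p = 0.0912). The cause was not tested.

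Single gene results were followed only for genes of the naming rule, called list members, genes called in both lines and members of some gene families. They do not stand for all called genes. Of 3005 alternatives for the 206 such results past 0.05, 2538 kept the call, 466 lost it, 1 had no adjusted p (CXCL5 in IGROV-1 by DESeq2) and 0 reversed. For genes that the naming rule took other than as list members, the shared genes included, these numbers were 908 of 980 kept and 72 lost. Of 255 alternatives for the 22 list results past 0.05, 202 kept the call and 53 lost it, or 201 of 233 and 32 without the estimated correlation. DESeq2 gave 653, 118, 406 and 15 genes for IGROV-1, SK-OV-3, the difference and both lines. Omitting both libraries of steepest trend gave 405 genes for the difference and 19 shared. At 20033197 to 31683936 counts per library the floor of 3 counts lay at 0.0947 to 0.15 CPM, so genes under about 1 CPM rest on few reads.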

Other observations

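The gene families and the relation to the baseline of the other line were tested only after the data were seen, the families being grouped by symbol stem, and their members were chosen after their values were seen. By camera with the preset correlation 6 of 453 families passed in IGROV-1 and 5 of 477 in SK-OV-3, and none did with an estimated correlation (adjusted p = 0.991 and 0.995). In IGROV-1 the symbols with the stem DLX, homeobox genes and the noncoding DLX6-AS1, had 4 of 7 members falling, with a median of -0.557 (camera adjusted p = 0.00439, and adjusted p = 0.991 with an estimated correlation), while DLX1 and DLX4 were higher without passing. Beside DLX6-AS1 the falling members were DLX5, from 125.4 ± 4.52 to 83.25 ± 3.52 CPM (log2 -0.59 ± 0.063, adjusted p = 6.44e-05), DLX6, from 99.81 to 67.97 CPM (-0.56, 0.000177), and DLX3, from 7.969 to 4.79 CPM (-0.73, 0.00162). DLX6-AS1, DLX6 and DLX5 lie together on chromosome 7 (96968515 to 97024831), and DLX3 lies on chromosome 17. DLX6 lies within the span of DLX6-AS1, and their reads may be shared. The falls are therefore mostly those of a single locus and not of the whole family. The stem MMP, matrix metalloproteinase genes and the antisense RNAs MMP24-AS1 and MMP25-AS1, had 5 of 12 members rising in IGROV-1, with a median of 0.298 (camera adjusted p = 0.00478, and adjusted p = 0.991 with an estimated correlation). Matrilysin, MMP7, rose from 352.4 ± 19.5 to 616.1 ± 43.7 CPM (0.81 ± 0.068, 1.21e-05) and MMP14 from 76.09 to 102.9 CPM (0.44, 0.00113), with MMP1, MMP2 (0.46, 0.0462) and MMP24 (0.31, 0.027) beside them. MMP2 and MMP24 lost their calls without any 1 of the DMSO libraries, MMP2 also without EPZ-5676 replicate 1 and MMP24 without EPZ-5676 replicate 2 (adjusted p from 0.0634 to 0.223).

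Genes of the HOXB cluster on chromosome 17 (48542655 for the start of HOXB2 to 48626358 for the end of HOXB9, with HOXB13 further along) had medians below 0 in both lines. The median was -0.231 in IGROV-1 and -0.181 in SK-OV-3, with 8 and 7 of 9 genes lower (camera adjusted p = 0.00439 and 0.00601, and adjusted p = 0.991 and 0.995 with an estimated correlation). In IGROV-1, HOXB3 fell from 139.5 to 115.7 CPM (-0.27 ± 0.057, adjusted p = 0.0142), HOXB6 by 0.30 (0.0257), HOXB8 by 0.30 (0.0421) and HOXB9 by 0.33 (0.00792), and adjusted over the family alone 7 fell. In SK-OV-3, HOXB3 fell by 0.25 (0.0401) and HOXB4 from 21.26 to 15.42 CPM (-0.47 ± 0.087, 0.00538), and 5 fell adjusted over the family alone. Without SK-OV-3 EPZ-5676 replicate 3 the family's call in that line ended (adjusted p = 0.0958). HOXB3, HOXB6 and HOXB8 lost their IGROV-1 calls without any 1 of the DMSO libraries or EPZ-5676 replicate 2, HOXB6 and HOXB8 also without EPZ-5676 replicate 1, and HOXB9 without DMSO replicate 2 (adjusted p from 0.0527 to 0.26). The SK-OV-3 call of HOXB3 ended without any 1 library other than EPZ-5676 replicate 2 (up to 0.243) and that of HOXB4 without DMSO replicate 3 (0.05).

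Among lists fixed beforehand that did not pass, single genes of drug efflux and of ovarian cancer stem cells rose in IGROV-1. The efflux pump ABCG2 went from 0.35 ± 0.0958 to 1.222 ± 0.102 CPM (3.49-fold, adjusted p = 0.00307), the 1 of 9 efflux genes to pass (2 adjusted over the list alone, camera adjusted p = 0.669, list median -0.0588, mean 0.245 and test direction upward). Of 14 stem cell genes, the receptor KIT rose from 7.816 to 11.85 CPM (0.00538) and the aldehyde dehydrogenase ALDH1A3 from 3.904 to 5.91 CPM (0.00907), whereas POU5F1 fell from 333.3 to 280.9 CPM (0.0327). Adjusted over the list alone 6 rose and 6 fell, with a median of -0.00833, a mean of 0.0396 and a test direction upward (camera adjusted p = 0.748). KIT and ALDH1A3 lost their calls without DMSO replicate 2 (0.0592 and 0.0598), and POU5F1 its call without any 1 library other than EPZ-5676 replicate 3 (up to 0.205).

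Genes that fell in IGROV-1 tended to be those already lower in SK-OV-3. Of the 206 genes that fell, 166 (80.6%) had a lower DMSO level in SK-OV-3 than in IGROV-1, against 46.2% of the remaining genes. Of the 371 that rose, 225 (60.6%) had a higher one, against 53.8%. In SK-OV-3 36 of 62 falling genes (58.1%) were lower in IGROV-1, against 53.4% of the remaining genes, and 12 of 40 rising genes (30%) were higher there, against 46.6%. These percentages took the baseline from the same DMSO libraries that made the calls, and the remaining genes were not matched on level. Part of each contrast may therefore come from the selection of the genes. Using a different IGROV-1 DMSO library for the baseline than for the response, the rank correlations across genes, which are not independent replicates, were 0.175, 0.163 and 0.201. For SK-OV-3 they were -0.0536, -0.0627 and -0.0562. This relation was noticed in the data, and its cause was not tested.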
